A study of Homo sapiens with 13 samples.

How the data were processed

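DNA-RNA immunoprecipitation sequencing (DRIP-seq) was carried out on U2OS cells, a human osteosarcoma line, after transfection with a control siRNA (siCtrl) or an siRNA against REXO4 or RNaseH1. The S9.6 antibody, which binds DNA-RNA hybrids, was used for the IP libraries. Per the labels' protocols, DNA was sonicated to fragments of roughly 500 bp before the IP, a second-strand synthesis step preceded library preparation, and the libraries were made as for ChIP. The series holds 13 samples. There are 3 S9.6 IP libraries per transfection (9 in all), 1 input library per transfection and 1 IgG library from siCtrl cells. Groups were taken from the sample titles.

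The files used were 3 peak lists, 1 per transfection. Per the labels and the file names, the authors merged the 3 IP libraries of a group before peak calling, so every deposited value is a pooled value with no SD or n. The submitters' processing notes name Trim Galore 0.6.10, HISAT2 2.2.1, Cufflinks, SAMtools 1.17, deepTools 3.5.1, MACS2 2.1.0.20150731 and the hg38 build, without their roles or options. The control library of each call and the treatment of duplicate and multiply mapped reads are not given in the sources used here. The lists have the 10 columns of the narrowPeak layout and no header. The deposited fold enrichment (a ratio) is the value at the summit over the caller's local background. The deposited −log10 p and −log10 q belong to the same summit. The deposited score is 10 times the −log10 q, truncated, except for 7 siRNaseH1 peaks. The lowest −log10 q was 1.34 in siCtrl, 1.32 in siREXO4 and 1.37 in siRNaseH1, just under a q-value of 0.05 in all the deposited lists. Apart from the recovery of coverage described below, a fold or score was used only to rank, filter or describe peaks within its own list. No read depth is given. Per-replicate, input and IgG signals were not analysed here.

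Peaks on chromosomes 1 to 22 and X were analysed. No peaks overlapped within a list, so each peak is 1 locus. A knockdown locus was called gained when no siCtrl peak overlapped it by at least 1 bp, and loci gained in both are siREXO4 gained loci that a siRNaseH1 gained locus overlapped by at least 1 bp. Shares carry 95% Wilson intervals, which cover counting error only and not the variation between cultures. With 1 merged list per transfection no test between conditions was possible, and no p-value is given. Overlaps were set against 1000 random placements of the siREXO4 gained loci on their own chromosomes, outside siCtrl peaks. Because no genome sequence was used, assembly gaps were approximated by leaving out stretches of over 1 Mb without any gene or peak, which left 2871.5 Mb.

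Gene positions and symbols came from a RefSeq gene table of GRCh38.p14, whose chromosome coordinates are those of hg38. The table has no strand or exon column. The planned classes of TSS, gene end, exon and intron were therefore replaced by 3 classes for the summit of a locus, in order of priority. These are within 2 kb of either boundary of any annotated gene, inside a gene but farther from a boundary, and between genes. For the same reason, a locus was given to the gene with the nearest boundary and not the nearest TSS. A gene was counted as holding a locus when the locus overlapped the gene or the 2 kb on either side.

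The comparisons, the gene lists and the rule for named genes were fixed before the data were examined. The rule took the 10 protein-coding genes with the highest fold within each gained set. For loci gained in both, it took the genes with the best lower rank of the 2 lists. It also took the 3 genes with the most gained base pairs per set, the 5 genes with the highest fold among siCtrl loci found in neither knockdown, up to 4 members per list (first those with a locus gained in both, then by fold), and REXO4 and RNASEH1 themselves. A gene that the rule names is not reported here. The 17 gene lists were each compared with 10000 random lists of the same size, matched on biotype and on decile of gene length. The number of random lists that reach the observed count describes these peak lists and is not a p-value. Matching did not include expression. Of 479 symbols, 478 were found.

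For comparisons of coverage between lists, the number of fragments at each summit was recovered from the fold and p-value columns. MACS2 writes fold as (fragments + 1) / (background + 1) and p as the upper Poisson tail, so 1 whole number of fragments and 1 background value satisfy both. All peaks with −log10 p below 300 gave a whole number within a tolerance of 0.001 in −log10 p. The lowest background of a list is its genome-wide expected coverage.

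Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 was used. The code was tested on simulated data. Among 10851 randomly placed loci, all 1000 loci planted on siRNaseH1 gained loci were recovered, and placed loci gave 0.868 times the mean overlap of further placements. The alternatives comprised stricter peaks, lists of equal length, other rules for overlap, merging and gain, other placements, other gene windows and unmatched random lists.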

Results

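DNA-RNA hybrids were mapped by DRIP-seq, an IP of sonicated genomic DNA with the hybrid-binding S9.6 antibody, in U2OS osteosarcoma cells. The cells had received a control siRNA (siCtrl) or an siRNA against REXO4 or against RNaseH1. RNaseH1 is a ribonuclease that degrades the RNA strand of DNA-RNA hybrids, and REXO4 is a member of the REXO family of predicted exonucleases. There were 3 S9.6 IP libraries per transfection, 1 input per transfection and 1 IgG library from siCtrl cells, 13 samples in all. The values come from 1 peak list per transfection, each called by the authors on the merged IP libraries. No value therefore has a replicate error, no test between transfections was possible, and read numbers are not given. The background coverage recovered from the peaks was 1.28 fragments in siCtrl, 1.41 in siREXO4 and 1.36 in siRNaseH1. The fold enrichment of a peak is the authors' own value within its list. Coordinates are those of hg38.

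REXO4 itself, on chromosome 9 from 133406058 to 133418172, held no peak in any of the 3 lists. RNASEH1, on chromosome 2 from 3531813 to 3558333, held no siCtrl peak. It held 1 siREXO4 peak, from 3536322 to 3536899 inside the gene, with a fold enrichment of 5.91. In the siRNaseH1 list it held 3 peaks, with fold enrichments of 6.0, 4.59 and 3.78. Peaks do not measure transcript or protein levels, so these values do not check the knockdowns.

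The number of loci with S9.6 signal in each transfection was compared first. On chromosomes 1 to 22 and X, the siCtrl list held 4458 loci, the siREXO4 list 12687 and the siRNaseH1 list 20954, which were 2.85 and 4.70 times the siCtrl number. They covered 1872 kb in siCtrl, 6580 kb in siREXO4 and 10699 kb in siRNaseH1. The median width was 336 bp in siCtrl, 383 bp in siREXO4 and 394 bp in siRNaseH1. When each list was limited to its 4458 peaks of lowest p-value, 3343 siREXO4 and 3372 siRNaseH1 loci had no siCtrl peak. At equal list length the loci lost follow from the loci gained, so the cut does not compare gain with loss.

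**Figure D1:**
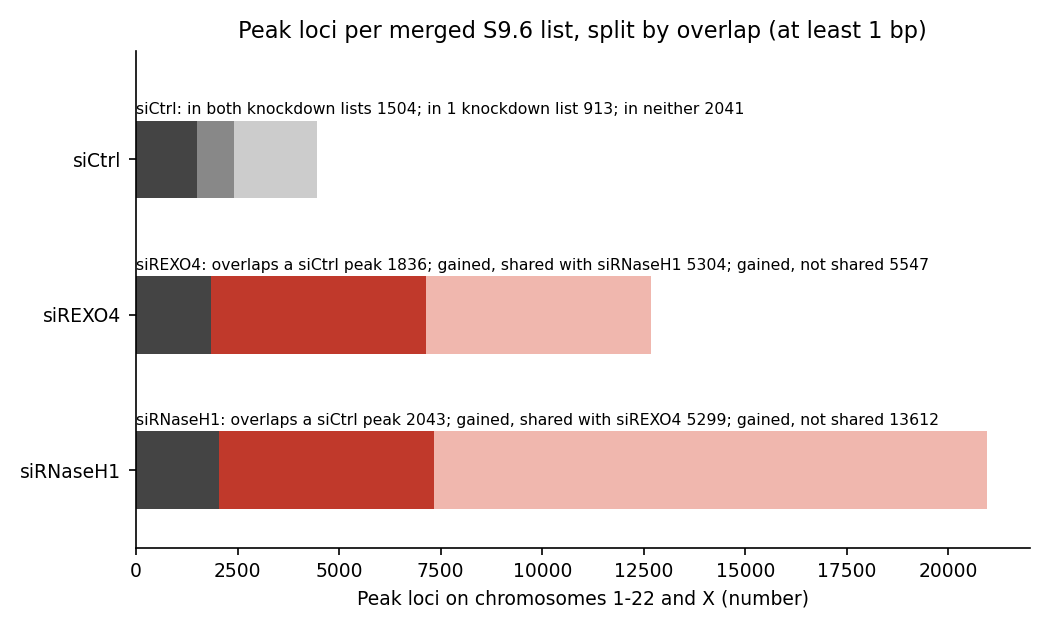
Number of peak loci on chromosomes 1 to 22 and X in the merged S9.6 list of each transfection. Bar segments split each list by overlap of at least 1 bp, with the count of each segment written above the bar; 5304 siREXO4 gained loci are shared with siRNaseH1.

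The question of where REXO4 knockdown adds S9.6 loci was addressed with the siREXO4 loci that no siCtrl peak overlapped. They numbered 10851, or 85.5% of the list (95% Wilson interval 84.9 to 86.1%). The highest fold enrichment was 148, at a 1548 bp locus inside CD8A, which encodes a T-cell coreceptor (chromosome 2, 86789323 to 86790870). At protein-coding genes, 95.2 came next, at a 2080 bp locus inside RREB1, a zinc finger transcription factor (chromosome 6, 7244743 to 7246822). Further leading loci lay within 2 kb of a gene boundary. They included SUPT20H, a SAGA complex component (40.7), the zinc finger gene ZFP91 (37.8), CDV3 (36.1), RAMP3 (35.3) and FBRS (33.7). PHB2, which encodes the mitochondrial protein prohibitin 2 (33.5), and ALG13, an N-glycosylation gene (33.3), were also among them. A second protein-coding gene lies at the ZFP91, FBRS and PHB2 loci. Each of these leading loci also overlapped a siRNaseH1 gained locus, with a fold in that list of 14.7 at CD8A and 10.9 at RREB1.

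By length, the gained loci at KDM6B, a histone H3K27 demethylase gene, were the longest in sum, at 6992 bp in 3 loci. LOC124904106, which overlaps KDM6B, held 6649 bp in 2 of them. NTSR1, the neurotensin receptor gene, held 6543 bp in 11 loci. A siREXO4 gained locus was found in 6251 of 19974 protein-coding genes, and 4876 of these genes held no siCtrl peak. Gained loci were densest on chromosome 19, at 14.5 per Mb, and on chromosome 17, at 9.35 per Mb, against 3.78 per Mb over all chromosomes and 1.29 on X. The siCtrl loci were also densest on chromosomes 17 (4.46 per Mb) and 19 (4.28), against 1.55 over all chromosomes and 0.23 on X. Of the gained loci, 17.2% reached 2 times the coverage needed for a call in siCtrl after scaling for background, and the median was 1.41 times that limit. At a fold enrichment of at least 5, 4685 loci had no siCtrl peak.

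**Figure D2:**
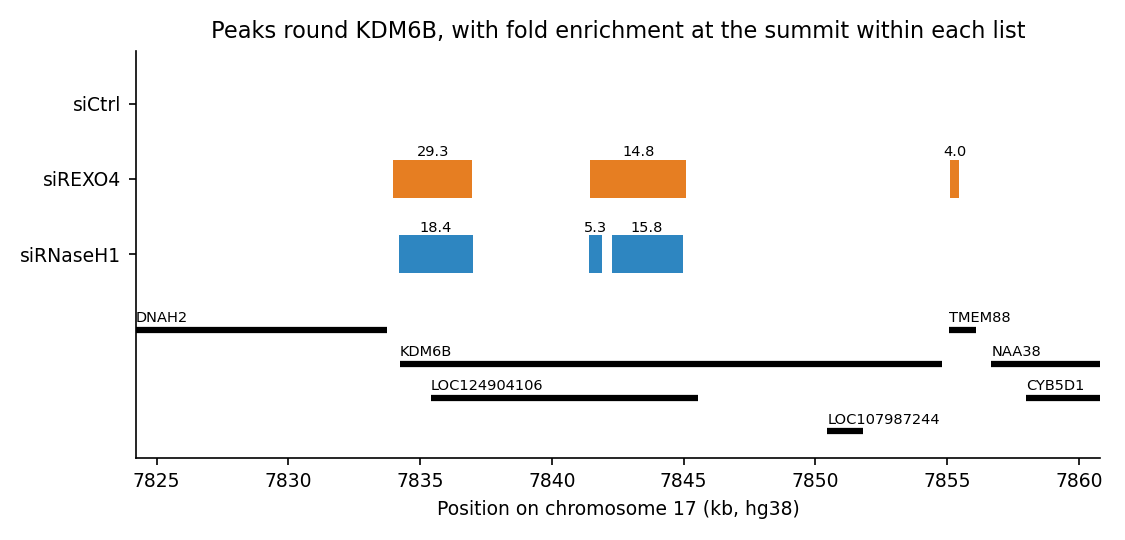
Peaks of the 3 lists round KDM6B on chromosome 17 (position in kb, hg38), with the fold enrichment within its list written above each peak and black bars for annotated genes. There is no siCtrl peak in the window, while siREXO4 has peaks of 29.3, 14.8 and 4.02 and siRNaseH1 of 18.4, 5.26 and 15.8.

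The same was done for RNaseH1 knockdown. The siRNaseH1 list held 18911 loci without a siCtrl peak, 90.3% of its loci (89.8 to 90.6%). The highest fold enrichment of these gained loci was 95.7, at a locus outside the ranking, which covers protein-coding genes only. At protein-coding genes, the leading locus was at FHL2, which encodes a LIM domain protein (61.2, chromosome 2, 105398172 to 105399447). KDM3A, a histone H3K9 demethylase gene, came next (58.5, chromosome 2, 86440852 to 86442241). FRMD4A (54.2) followed, also inside the gene. Loci within 2 kb of a gene boundary were at TBRG4 (50.2), ALG13 (49.3), PHB2 (45.3), EXT1, a heparan sulfate synthesis gene (45), PITPNA (44.7), PLXNA3 (44.5) and CLU, which encodes the chaperone clusterin (40.0). A second protein-coding gene lies at the PHB2 and PITPNA loci. Each of these leading loci also overlapped a siREXO4 gained locus, with a fold in that list of 13.7 at FHL2 and 6.82 at FRMD4A.

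The longest gained sequence in sum was in 3 genes with long annotated spans, of 1227 kb for GPHN, 864 kb for VPS13B and 1123 kb for RANBP2. Each sum covers the whole span in the gene table, and other genes within a span were not told apart. GPHN, the gephyrin gene, held 13318 bp in 32 loci, VPS13B 12220 bp in 27, and the nucleoporin gene RANBP2 11858 bp in 22. Of all protein-coding genes, 106 held 10 or more siRNaseH1 gained loci, against a mean of 37.5 and a maximum of 46 over 20 random placements, while 4 genes did so for siREXO4 (mean 6.90). For siCtrl loci, 3 genes did so, against a mean and a maximum of 0. A gained locus was found in 7514 protein-coding genes, of which 5833 held no siCtrl peak. The density was again highest on chromosome 19 (21.2 per Mb) and chromosome 17 (13.9), against 6.59 over all chromosomes and 2.34 on X. Of the gained loci, 23.3% reached 2 times the siCtrl calling limit, and the median was 1.55 times. At a fold enrichment of at least 5 they numbered 9982.

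Whether both knockdowns add loci in the same regions is the question the series design names. Of the 10851 siREXO4 gained loci, 5304 (48.9%, 47.9 to 49.8%) overlapped a siRNaseH1 gained locus. Random placements gave a mean of 85.6 with an SD of 9.70 and a maximum of 117. The observed number was 61.9 times the mean, and none of the 1000 placements reached it. Of the 1836 siREXO4 loci with a siCtrl peak, 1486 (80.9%) overlapped a siRNaseH1 locus, a higher share than among gained loci. Of all siCtrl loci, 41.7% overlapped a siREXO4 peak and 46.3% a siRNaseH1 peak. These overlaps were not set against placement, so the ratio of 61.9 does not tell shared gain from overlap common to S9.6 lists. In the other direction, 5299 of 18911 siRNaseH1 gained loci (28.0%, 27.4 to 28.7%) overlapped a siREXO4 gained locus. Ranked by the lower of their ranks in the 2 lists, PHB2 and ALG13 came first. They were followed by KDM3A, with fold enrichments of 30.7 in the siREXO4 list and 58.5 in the siRNaseH1 list, and by CARS2, a mitochondrial cysteinyl-tRNA synthetase gene, with 28.9 and 29.5. The others were ZNF487 (23.9 and 33.3), MAGEA2B (22.5 and 30.5), the transcription termination factor gene PCF11 (21.6 and 29.4), the acetyltransferase gene EP300 (27.4 and 25.9), PURB (21 and 28.5) and RAB1A (24.7 and 25.1). MAGEA2B has near-identical copies, so its locus is uncertain. At KDM6B, 2 siREXO4 gained loci with a summed width of 6649 bp overlapped siRNaseH1 gained loci, from 7833969 to 7836985 and from 7841461 to 7845092 on chromosome 17. At LOC107984156 such siREXO4 loci summed to 4617 bp.

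Overlap was more frequent at loci of higher fold enrichment. With siREXO4 gained loci split by fold into 4 equal groups, it was 33.5% in the lowest, then 37.0%, 44.3% and 80.7% in the highest. For siRNaseH1 the same split gave 17.3%, 18.1%, 23.6% and 53.1%. Both kinds of gained locus occurred in 5002 protein-coding genes, against 2540 for independent lists within 100 groups of genes of like length (1.97 times), and 4156 genes held a locus gained in both. The same siCtrl list defines both gained sets, and part of the excess may reflect that. Placement within 100 kb of each locus lowered the ratio to 18.1.

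The location of the summits differed between the sets. Of loci gained in both, 61.0% (59.7 to 62.3%) lay within 2 kb of a gene boundary, against 13.5% of randomly placed loci. The share was 44.5% for all siREXO4 gained loci, 34.7% for all siRNaseH1 gained loci and 27.9% for siCtrl loci. It was 52.0% for siCtrl loci present in all 3 lists and 13.6% for those in neither knockdown, so a high share was not particular to gained loci. Loci gained in siRNaseH1 and not in siREXO4 lay inside genes in 64.5%, against 51.3% at random, and within 2 kb of a boundary in 24.5%. Those gained in siREXO4 and not in siRNaseH1 lay near a boundary in 28.6%, inside genes in 49.0% and between genes in 22.4%. Between genes, the shares were 15.3% for siREXO4 gained, 10.1% for siRNaseH1 gained and 24.6% for siCtrl, against 35.4 to 35.7% at random. The gene table has no strand, so a TSS and a gene end were not told apart. Only the outer boundaries of each gene were used, so a TSS farther within a gene was counted as inside it.

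**Figure D3:**
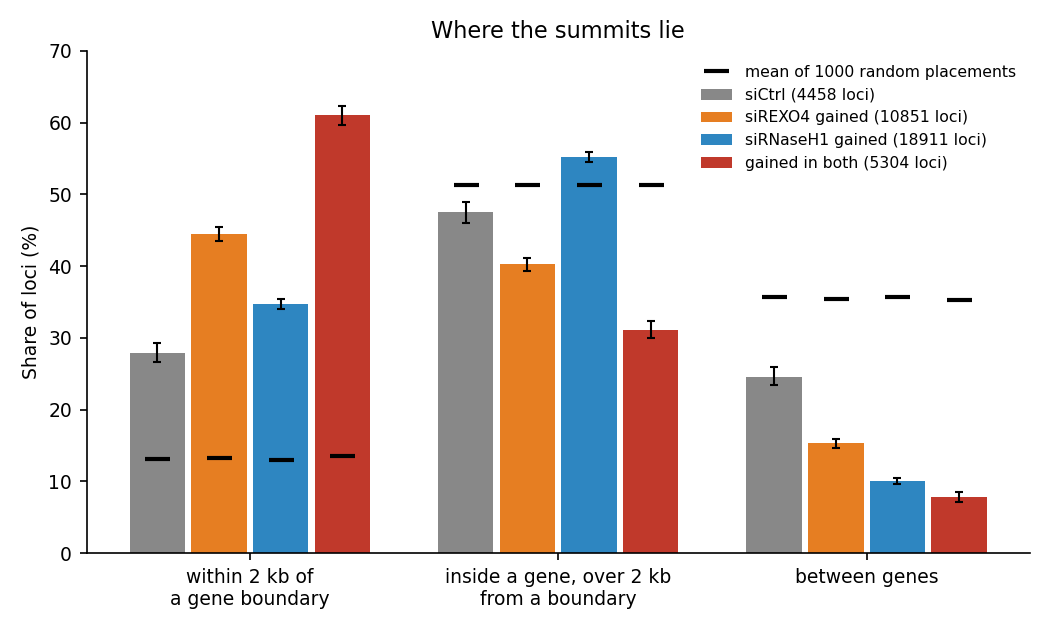
Share of loci (%) whose summit lies within 2 kb of a gene boundary, inside a gene farther from a boundary, or between genes. Bars are the siCtrl, siREXO4 gained, siRNaseH1 gained and gained in both sets, error bars are 95% Wilson intervals and black dashes are the means of 1000 random placements; loci gained in both reach 61.0% near boundaries.

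Genes of the translation machinery held gained loci more often than random genes of like length. Among 79 cytosolic ribosomal protein genes, 46 held a siREXO4 gained locus (random mean 17.7), 72 a siRNaseH1 gained locus (20.5) and 43 a locus gained in both (13.1), and none of 10000 random lists reached these counts. Of the same genes, 40 held a siCtrl locus (5.26). The leading siRNaseH1 gained loci had fold enrichments of 19.2 at RPL3, 18.1 at RPS27 and 15.1 at RPS10. RPL41 reached 14.7 in the siREXO4 list, from 56117621 to 56118612 on chromosome 12. A siCtrl peak of 11.5 lay next to that locus, from 56116309 to 56117372. Of 38 ribosome biogenesis and nucleolar genes, 36 held a siRNaseH1 gained locus (14.1) and 19 a siREXO4 gained locus (11.5). GNL3, the nucleostemin gene, had a siREXO4 locus of 20.8, NOP10 a siRNaseH1 locus of 16.8 and NCL, the nucleolin gene, 5 loci gained in both. Of 18 snoRNA host genes, 14 held a siRNaseH1 gained locus (1.92) and 9 a siREXO4 gained locus (1.71), including SNHG3, SNHG29 and DANCR. A siCtrl locus was found in 6 snoRNA host genes (0.50) and in 10 ribosome biogenesis genes (4.05). RPS10, RPL41, NCL and SNHG3 are among the named genes that also held a siCtrl locus elsewhere in the gene or its flanks.

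Stress and growth response genes followed. Of 22 immediate early genes, 14 held a siREXO4 gained locus (4.86) and 14 a siRNaseH1 gained locus (5.59). There were also 14 with a siCtrl locus (1.46). KLF2 had gained loci of 15.6 in siREXO4 and 22 in siRNaseH1, ATF3 of 13.2 and 15.1, and FOS of 9.33 and 17.6. These FOS loci lay outside the annotated gene, in its 2 kb flank. Of 20 p53 target genes, 14 held a gained locus in each knockdown (6.25 and 7.69) and 12 held a locus gained in both (4.37). The loci at XPC had fold enrichments of 19.6 and 22 and those at CDKN1A, the p21 gene, of 16.7 and 20.5. Of 15 heat shock and chaperone genes, 9 held siREXO4 and 13 siRNaseH1 gained loci (3.94 and 4.71), with 16.2 at HSPA5 and 18.2 at HSP90B1 in the siRNaseH1 list. A siCtrl locus was found in 6 heat shock genes (1.25, reached by 11 random lists) and 6 p53 target genes (2.16, reached by 173). Within 2 kb of a gene boundary these counts were 3 (0.76, reached by 350) and 1 (1.07, reached by 6641), while 12 p53 target genes held a gained locus there in each knockdown (4.74 and 5.62). FOS, ATF3, XPC, HSPA5 and HSP90B1 also held a siCtrl locus.

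Genes of genome maintenance gave mixed counts. Of 36 replication genes, 21 held siREXO4 and 25 siRNaseH1 gained loci (12.2 and 14.9), among them RPA2 (11.3 and 11.2) and RFC3 (8.66 and 12.6), and 9 a siCtrl locus (4.49, reached by 271 random lists). Within 2 kb of a boundary the counts were 17 and 22 (8.52 and 10.1), and 7 for siCtrl (1.77, reached by 16). Of 35 R-loop processing factors, 18 and 23 did (12.2 and 15), and 309 and 36 of the 10000 random lists reached these counts. Counted only within 2 kb of a gene boundary, 8 and 13 did (8.11 and 9.91), which 5846 and 1704 random lists reached. DHX9, a helicase that unwinds DNA-RNA hybrids, had loci of 24.9 and 13.4, MUS81 of 10.2 and 22, and BRCA1 of 9.08 and 12.5. These MUS81 and BRCA1 loci lay outside the annotated genes and were counted through the 2 kb flanks. Of 22 telomere genes, 15 held a siRNaseH1 gained locus (8.66), while 9 held a siREXO4 gained locus, which 2487 random lists reached. Within 2 kb of a boundary the siRNaseH1 count was 9 (5.58), which 764 random lists reached, against 37 for the whole gene. TERF2 had loci of 13.9 and 17.8. Of 67 replication-dependent histone genes, 24 and 20 held gained loci (10.5 and 11.7) and 14 a siCtrl locus (2.73). Without matching, 121 random lists reached the siRNaseH1 count (mean 11.9), against 66 with it. A siCtrl locus was found in 9 R-loop processing factors (4.76) and 2 telomere genes (2.85). Of the named genes, DHX9, RPA2, H2AC19 and H3C15 also held a siCtrl locus. H2AC19 and H3C15 share 1 locus, so neighbouring histone genes are not independent.

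The remaining lists went both ways. Of 250 ZNF genes on chromosome 19, 53 held siREXO4 and 64 siRNaseH1 gained loci, against random means of 80.2 and 99, and all 10000 random lists reached these counts. Against random lists drawn from all genes without matching, the same counts lay above the means of 37.0 and 44.6. Those lists mix biotypes, while these ZNF genes are all protein-coding. Of all protein-coding genes, 31.3% held a siREXO4 and 37.6% a siRNaseH1 gained locus, against 21.2% and 25.6% of the ZNF genes. The ZNF counts were thus low against their own biotype also without matching on length. ZNF787 had loci of 14.9 and 21.1. Of 30 genes of other tissues, 2 held a gained locus in each knockdown (7.27 and 8.55, or 4.47 and 5.37 without matching, where the siRNaseH1 count is no longer in the lowest 1% of random lists). These were CRYAA (9.06) and CD4 (3.47) in siREXO4, and HBA1 (4.97) and TG (4.34) in siRNaseH1. Of 26 interferon-stimulated genes, 4 and 5 held gained loci (7.48 and 9.10, or 3.84 and 4.63 without matching), including STAT2 (18.3 and 21.2) and ISG15 (8.52 and 12.6). Of 22 osteosarcoma and mesenchymal genes, 3 and 6 did (7.22 and 8.50, or 3.26 and 3.95 without matching), including RUNX2, the osteoblast transcription factor gene (4.98 and 6.17). Within 2 kb of a gene boundary, 1 and 1 did (4.61 and 5.62). Of 23 common fragile site genes, 8 and 7 did (9.50 and 10.4, or 3.44 and 4.07 without matching), and 1, WWOX, held a locus gained in both. Near a boundary the fragile site counts were 1 and 1 (3.18 and 4.24). Of 16 loci often assayed for R-loops, 8 and 10 did (4.32 and 5.09), among them RPL13A (5.98 and 14.2), and 7 held a siCtrl locus (1.48). The gained counts were reached by 407 and 103 random lists, so neither was in the highest 1%, and the siCtrl count by 7. Of 18 abundant noncoding RNA genes, 6 and 10 did (2.09 and 5.28), and 8 held a siCtrl locus (3.70). Without matching, 422 random lists reached the siREXO4 count (mean 2.67), against 72 with it. The means without matching were 3.22 for siRNaseH1 and 1.06 for siCtrl. A biotype with few genes leaves few or no other genes to draw, so the matched lists can hold the members themselves. Members with gained loci included NORAD (5.09 and 13.1) and NEAT1 (7.15 and 10.8). NEAT1 also held a siCtrl peak of 31.2, from 65422262 to 65423667 on chromosome 11, next to its gained loci. A siCtrl locus was also found in 15 ZNF genes (26.6), 6 fragile site genes (5.52), 1 gene of other tissues (2.45), 1 osteosarcoma and mesenchymal gene (2.97) and 0 interferon-stimulated genes (2.41). Expression was not matched in the random lists, and genes of a list that are transcribed in U2OS cells were not told from silent ones.

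**Figure D4:**
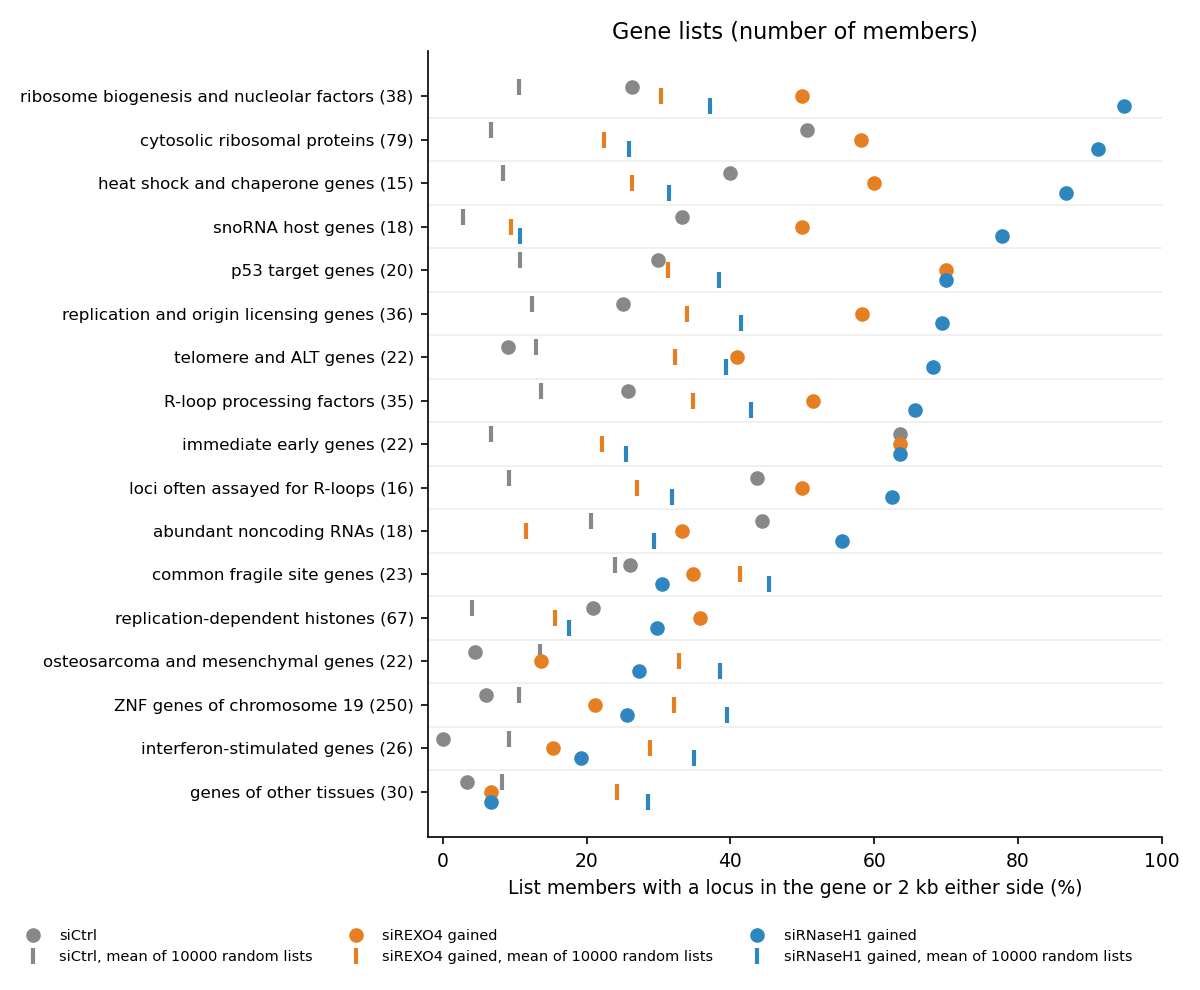
Members (%) of each of the 17 gene lists, with list size in brackets, that hold a locus in the gene or the 2 kb either side. Circles are the siCtrl, siREXO4 gained and siRNaseH1 gained sets and ticks of the same colour the means of 10000 random lists; 72 of 79 ribosomal protein genes hold a siRNaseH1 gained locus.

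Loss of control loci was examined from the siCtrl side. Of 4458 siCtrl loci, 1859 (41.7%, 40.3 to 43.2%) overlapped a siREXO4 peak, 2062 (46.3%, 44.8 to 47.7%) a siRNaseH1 peak, 1504 (33.7%) both and 2041 (45.8%) neither. Split by fold enrichment into 4 equal groups, 72.9% of the highest group overlapped at least 1 knockdown peak, against 48.0% of the lowest group. The siCtrl loci in neither knockdown had fold enrichments of at most 7.94. The highest were inside or near FZD6 (7.94, a Frizzled receptor gene), UAP1 (7.91), ANKRD55 (7.91), COL6A6 (7.5) and UACA (7.5). They lay within 2 kb of a gene boundary in 13.6%, close to the 12.6% of random placement, whereas siCtrl loci present in all 3 lists did so in 52.0%. A required reciprocal overlap of 50% lowered the kept shares to 23.8% for siREXO4 and 24.3% for siRNaseH1.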

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

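The tests of sequencing depth, of sampling noise at the calling limit and of the share of siCtrl loci between genes, with its other rules for gaps, were chosen only after their results or related values had been seen, whereas placement within 100 kb was fixed beforehand and only its bounds were set afterwards.

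Outside chromosomes 1 to 22 and X, the siREXO4 list held 470 peaks and the siRNaseH1 list 620, against 167 in the siCtrl list, on sequences that the comparisons do not use. On alternate sequences there were 343 in siREXO4, 506 in siRNaseH1 and 75 in siCtrl.

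The siCtrl list was shorter than both knockdown lists. Lower sequencing depth of the merged siCtrl libraries, measured as coverage, is argued against. The background coverage recovered from the siCtrl peaks was at least 0.906 times that of either knockdown. Read numbers and the options of the calls are not given, so depth in reads was not compared. Sampling noise at the calling limit with no difference in coverage predicts lists of about equal length at 1 common p. At that p the siREXO4 list held 12549 loci and the siRNaseH1 list 20805, against 4458 in siCtrl. The lower ratio was 2.81 (95% interval from 2.72, counting error only), so unequal p limits do not account for the shorter list. The common p was the limit of the siCtrl list and left nearly all loci in place, since the full lists gave 2.85. The ratio thus restates the list lengths and does not decide on sampling noise. That siREXO4 gained loci were narrowly missed in siCtrl stays open, since 17.2% of them reached 2 times the siCtrl calling limit, and for siRNaseH1 the share of 23.3% fell between the bounds set beforehand and does not decide. A difference in IP efficiency between transfections, and an effect of the knockdowns on hybrids, may each explain the pattern and were not tested.

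The siREXO4 and siRNaseH1 gained loci overlapped more often than placed loci. A shared density over larger regions is argued against, since the overlap was 18.1 times that of loci placed within 100 kb. A general preference for gene boundaries is argued against as well. Of 4825 siREXO4 gained loci near a boundary, 3237 overlapped, 9.70 times the mean of 334 for the same loci moved to other protein-coding gene boundaries. A preference for transcribed or GC-rich boundaries, and the shared siCtrl list, may contribute and were not tested.

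Among siCtrl loci that neither knockdown overlapped, the share near a gene boundary was 1.07 times that of random placement, within the bound of 1.2 set beforehand for scattered background calls, so these stay open. Their share between genes was 0.869 times that of placement (31.2% against 35.8%), and none of 1000 placements was as low. That share does not decide, because assembly gaps were only approximated. With stretches of over 500 kb without a gene or peak left out, in place of 1 Mb, the ratio was 0.894 and with 300 kb 0.947, where 56 of 1000 placements were as low. There were 29 windows of 1 Mb with 5 or more such loci, 5.09 times the mean of 5.70 for random placement, so a regional component such as copy number or local background may contribute and stays open. The window with most, 7 loci, was on chromosome 17 from 75000001 to 76000000. No biological explanation was tested.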

How the results depend on the processing

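The alternative with gained loci at 2 times the siCtrl calling limit, the gene list window at either boundary and the rules for gaps of 500 and 300 kb were chosen after seeing the data. No paired analysis was possible because each list was called on merged libraries and carries no replicate number, so leaving out replicates was not run either. Placement matched on GC content and a window at the TSS alone were not run, for want of a genome sequence and strand. Of 87 alternative values, 40 stayed within the counting interval or 1.5 times the count, 47 moved and 0 reversed; the causes were not tested. Read numbers are not given, so a missing siCtrl peak was judged only against the recovered background coverage. Of 27 gene list counts in the 3 gained sets that under 1% of random lists reached, 3 were lost with the boundary window and 2 without matching. Without matching, which draws from all genes, 11 of 51 counts changed from below to above the random mean and all 5 low counts were lost. With the boundary window, 1 of 51 changed sides. Of 17 siCtrl counts, 8 lay above and 1 below by the same rule. The boundary window ended 1 of the 8, for heat shock genes, and the low one for ZNF genes. It turned the p53 target count to below the random mean and added the replication genes to the counts above (7 against 1.77).

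At −log10 q of at least 3, siCtrl loci kept were 43.8% (siREXO4) and 49.6% (siRNaseH1), the shared gained share 53% and the ratio to placement 69.3. At fold 5 or more, loci numbered 1837, 5937 and 11492 (siCtrl, siREXO4, siRNaseH1), gained loci 5179 and 10636, the shared share 54.2% and the ratio 96.7. With lists of 4458 peaks each, gained loci were 3343 and 3372, kept shares 25.8% and 25.1% and the ratio 201. Reciprocal overlap of 50% gave kept shares of 23.8% and 24.3%, a shared share of 38.5% and a ratio of 179 (100 placements). Summits within 500 bp gave 40.1%, 44.1% and a ratio of 59.7. With no siCtrl peak within 5 kb, the shared share was 47.7% and the ratio 70.6. Knockdown fold of at least 5 against all siCtrl peaks gave 4685 and 9982 gained loci, 52.3% and a ratio of 105. Placement within 100 kb gave a ratio of 18.1 and within the same kind of location 51.4. At 2 times the siCtrl calling limit, gained loci were 1868 and 4397, the shared share 67.1% and the ratio 211. The boundary shares (siREXO4 gained, siRNaseH1 gained, both) were 35.9%, 25.4% and 52.8% at 1 kb, 45.8%, 36.5% and 62.3% for any overlap, and 36.7%, 28.4% and 53.7% with protein-coding genes only.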

Other observations

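tRNA, snoRNA, snRNA and miRNA genes also held gained loci more often than placed loci. Of 443 tRNA genes, 33 lay at a siREXO4 gained locus and 50 at a siRNaseH1 gained locus, against placement means of 8.60 and 14.8. Of 1196 snoRNA genes, 86 and 183 did (22.4 and 37.7), and of 154 snRNA genes 28 and 32 (4.34 and 6.81). Of 1911 miRNA genes, 103 and 173 did (40.0 and 65.6). Of 49 rRNA genes, 8 and 0 did (0.77 and 1.36), and the difference between the knockdowns was not tested. A siCtrl locus was found at 27 tRNA, 63 snoRNA, 28 snRNA, 52 miRNA and 29 rRNA genes. The siCtrl counts were not set against placement, so the excess cannot be called particular to gained loci. These genes often lie inside or near other genes. Of 18177 lncRNA genes, 1776 held a siREXO4 gained locus (1711), 1926 a siRNaseH1 gained locus (2713) and 1065 a locus gained in both (906).

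Repeated sequence held peaks in all 3 lists. The rRNA region of chromosome 21, from 8155988 to 8496572, held 60 siCtrl, 61 siREXO4 and 70 siRNaseH1 peaks. In the same order, these peaks covered 100982, 98959 and 83809 bp, and their highest folds within their own lists were 42.7, 37.6 and 31.2. A copy of mitochondrial sequence on chromosome 1 held 3, 5 and 3 peaks, and the mitochondrial genome was 1 peak of 16569 bp in each list. Reads in such sequence cannot be placed with certainty.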
